A study of Mus musculus with 6 samples.

How the data were processed

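Gene expression was measured in memory B cells carrying the immunoglobulin isotype IgG2b, sorted from the spleen or the bone marrow of mice that were either of the inbred C57BL/6J strain or bought from a pet shop. Per the labels' protocols, B cells were first enriched with magnetic beads against CD19 and then sorted as small living lymphocytes positive for IgG2b, CD19 and CD38 and negative for IgM, IgD, CD138, CD11c and GL7. The 6 arrays fell into 4 groups: 2 of C57BL/6J bone marrow, 2 of C57BL/6J spleen, 1 of pet shop bone marrow and 1 of pet shop spleen. The titles of the pet shop arrays name CD38 and give another isotype, IgG2ab, than the titles of the C57BL/6J arrays, while the other labels give IgG2b for all arrays. The groups here follow the latter, and the labels leave open whether the sort was the same for both origins. Arrays are numbered within their group, so the pet shop spleen array is number 1 here although its title calls it replicate 2. The labels do not say whether the 2 C57BL/6J arrays of a tissue come from separate animals or pools, or how many mice stand behind an array.

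The authors deposited intensity values, 1 linear signal per probe set and array, from Affymetrix MG 430_2 arrays, and per the submitters' processing notes the signals came from GCOS, which the series' design text gives as version 1.4. The signal algorithm and detection calls are not given in the sources used here. The labels describe RNA extraction and amplification in more than 1 way, so the kit and the RNA input are left open. On every array the mean of the deposited intensity values was 100.0 after trimming 2% of the probe sets at each end, so the arrays had been scaled to a common mean but not to a common distribution. Values ran from 0.0225 to 78481.1, and no depth of counting stands behind them; the number of arrays limits the precision.

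Of 45101 probe sets, 34958 had exactly 1 gene symbol in the platform annotation, 932 had several and 9211 had none there, the last including 64 array controls. Gene identifiers of 34754 of the 34958 were found in the reference gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table also gave the order of genes along chromosomes. Genes missing from the annotation, among them those for the sort markers CD19 and CD38 and for the IgG2b constant region, were not analysed here.

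Signals were transformed as log2(signal + 16) with the authors' scaling kept. Each gene was represented by the probe set with the highest mean over all arrays, and the 50% of the 18194 genes with the highest means were tested, which left 9097 genes with a mean log2 value of at least 5.47. Fold changes on this scale understate the change of genes with low signals. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and Benjamini-Hochberg adjusted p-values under 0.05 were called. The tissue difference (bone marrow minus spleen) and the origin difference (pet shop minus C57BL/6J) came from 1 additive model of both factors with 3 residual degrees of freedom. Whether the tissue difference itself differed between origins came from a model with 4 group means and 2 residual degrees of freedom. In that model the whole estimate of the spread comes from the C57BL/6J arrays, and the lone pet shop arrays are assumed to vary like them.

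Before the data were examined, 34 gene lists were written down: B cell states, other cell types that the sort could hold, pathways, and sex-linked genes as a check. The 28 with at least 5 tested members were tested with camera, using its preset inter-gene correlation of 0.01. A second run estimated the correlation from the residuals, and fry asked whether the genes of a list move on balance one way. The run with an estimated correlation also uses the 3 residual degrees of freedom, so its p-values can rise without any correlation. For marginal zone genes between tissues the estimate was -0.0209, yet the unadjusted camera p went from 1.19e-10 to 0.00644. The groups, models, alternatives and the rule for naming genes were fixed at the same time as the lists. The rule took the 12 called genes with the largest tissue difference in each direction that had the same sign in both origins, the 10 in each direction for origin with the same sign in both tissues, and the 3 in each direction with the smallest p for the difference between origins. For lists it took up to 4 called members, or the 3 with the largest differences where none was called. Fos, Jun, Egr1, Cd69 and Xist were always reported, and predicted genes without a regular name were skipped.

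Alternatives covered quantile normalization, a common median for all arrays, pseudocounts of 1 and 64, no filter or the upper 30% of genes, eBayes without a trend or with robust estimation, testing every probe set, other covariates, C57BL/6J arrays alone, blocks of arrays sharing a replicate number, and leaving out each array in turn. Leaving out the 2 arrays with the highest Gapdh 3'/5' ratio, a covariate for the actin 3'/5' ratio and a block of crossed replicate numbers were added after the data had been seen.

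The model code was tested on simulated arrays with the real gene means and the residual spread as moderated by eBayes, in which 200 of 9097 genes were changed. For tissue it called 85.2% of changes of 1 log2 unit and 99.8% of changes of 2 units, and for origin 81.4% and 99.8%. For the difference of the tissue difference between origins it called 7.7% of changes of 1 unit and 73.4% of changes of 2 units. False calls made up 7.1%, 7.4% and 9.5% of calls in the 3 comparisons. A list of 20 genes shifted by 0.5 between tissues was called in 20 of 20 runs. All genes were drawn independently of each other. The runs therefore do not show how camera errs on lists of correlated genes, where estimated correlations reached 0.874. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.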

Results

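The 6 arrays describe IgG2b-positive memory B cells, antigen-experienced B cells that have switched their antibody class, from the spleen and bone marrow of C57BL/6J mice (2 arrays per tissue) and of pet shop mice (1 array per tissue). Across genes, arrays correlated with Pearson's r between 0.895 and 0.976, and the first principal component, with 50.6% of the variance, separated pet shop from C57BL/6J arrays. Because the labels do not say that arrays of a group come from separate animals, the p-values of single genes measure only the spread between these arrays. The camera p-values with the preset correlation instead compare the genes of a list with all other genes, taken as nearly independent. They can therefore be very small with few arrays. Median signals lay between 13.8 and 21.9. The ratio of the 3' to the 5' Gapdh control, a measure of RNA integrity and amplification, was 68.8 on pet shop spleen 1 and 6.72 on C57BL/6J bone marrow 1, and between 1.28 and 2.06 on the others. The same ratio for actin was 4.76 on C57BL/6J bone marrow 1 and between 1.45 and 2.16 elsewhere, with 1.54 on pet shop spleen 1. The 18S ribosomal RNA control read 54.8 and 21.2 on the pet shop arrays against 368 to 638 on the C57BL/6J arrays.

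The series title sets IgG2 memory B cells of the spleen against those of the bone marrow, and the first comparison addresses this. S100a9 and S100a8, the subunits of calprotectin in granulocytes, were higher in bone marrow by 4.17 ± 0.36 and 3.74 ± 0.36 on the log2 scale (SE, 3 arrays against 3). Rag1, which encodes a recombinase of developing lymphocytes, was higher by 2.94 ± 0.24. The sphingosine 1-phosphate receptor gene S1pr3 was lower in bone marrow, with a difference of -3.23 ± 0.33, and Cr2 with -2.33 ± 0.14. Of 9097 genes, limma called 29, 12 higher and 17 lower in bone marrow.

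Each of the 12 genes higher in bone marrow had a higher signal on all 3 bone marrow arrays than on any of the 3 spleen arrays, a separation that 10% of random orders of 6 arrays give in either direction. The granulocyte list had 6 tested members, of which 4 were called higher (6 adjusted over the list alone): S100a9, S100a8, Ngp (2.64 ± 0.37) and Camp (1.64 ± 0.27), the last 2 encoding granule proteins. Its adjusted p was 4.58e-15 with camera and 0.177 with an estimated correlation. Mean S100a9 signal was 444 in bone marrow and 12.8 in spleen, and mean S100a8 signal 857 and 56.3. The list of pro-B and pre-B cell genes had 11 tested members and 4 calls, all higher (7 adjusted over the list alone). These were Rag1, Vpreb1 (2.54 ± 0.24) and Igll1 (1.86 ± 0.22), the latter pair encoding the surrogate light chain, and Sox4 (2.53 ± 0.24), a transcription factor of early B cells; adjusted p was 5.49e-15, and 0.177 with an estimated correlation. In the list of monocyte, macrophage and dendritic cell genes 1 of 11 was called higher (6 adjusted over the list alone), the lysozyme gene Lyz2 at 2.75 ± 0.40, with an adjusted p of 8.91e-06, and 0.202 with an estimated correlation. The sort had selected for CD19 and IgG2b, which granulocytes, monocytes and B cell precursors do not carry together.

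Among the other genes higher in bone marrow was Jchain, encoding the chain that joins polymeric antibodies, at 1.96 ± 0.29. It was the 1 called member of 15 in the plasma cell list, which was not called (adjusted p = 0.907, and 0.938 with an estimated correlation; 1 higher adjusted over the list alone). Atp1b1, a sodium pump subunit, and Selenop, a selenium transport protein, differed by 1.47 ± 0.23 and 1.45 ± 0.18. Proliferation genes had no called member among 19 (0 adjusted over the list alone), but the list was called higher with an adjusted p of 5.61e-05, and 0.405 with an estimated correlation; Rrm2, Cdk1 and Birc5 had differences of 0.88, 0.87 and 0.65. The quiescence list, with 0 of 20 members called (1 higher adjusted over the list alone), was also called higher at an adjusted p of 3.09e-05, and 0.177 with an estimated correlation. Its largest differences were 0.79 for Pik3ip1, 0.78 for Slfn2 and 0.70 for Cdkn2d. Erythroid genes, with 0 of 6 members called (0 adjusted over the list alone), had an adjusted p of 0.0321, and 0.234 with an estimated correlation; Slc4a1 and Car2 stood at 0.63 and 0.62.

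Among the genes lower in bone marrow, Cr2 was lower on each of the 3 bone marrow arrays (mean signal 318) than on each spleen array (mean 1680). Marginal zone B cells are splenic B cells with abundant Cr2; of 13 tested genes in their list 3 were called lower (5 adjusted over the list alone), namely S1pr3, Cr2 and Dtx1 (-1.15 ± 0.15), a Notch regulator, of which another probe set gave -0.29. The list's adjusted p was 1.11e-09, and 0.177 with an estimated correlation, and 12 of its 13 members had negative differences. The Notch list, which shares Dtx1, had 1 of 9 members called lower (2 adjusted over the list alone) and an adjusted p of 0.0017, or 0.177 with an estimated correlation. In the chemokine and lysolipid receptor list S1pr3 was the 1 called member of 18 (4 lower adjusted over the list alone), with an adjusted p of 1.99e-04 for the list, and 0.177 with an estimated correlation.

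The NF-kB list had 2 of 16 members called lower in bone marrow, the cytokine gene Tnf (-1.93 ± 0.26) and the activation marker Cd83 (-0.96 ± 0.13), and 6 adjusted over the list alone. Its adjusted p was 3.01e-04, and 0.214 with an estimated correlation. Myc was lower by -1.51 ± 0.20, but camera did not call the immediate early list that holds it (1 of 25 members called, 2 lower adjusted over the list alone; adjusted p = 0.325, and 0.443 with an estimated correlation). With fry, which does not compare a list with other genes, this list was called lower at an adjusted p of 0.00921, while its median was 0.01. Fos, Jun, Egr1 and Cd69 had differences of 0.27, -0.19, -0.61 and 0.01, none of them called. Other genes called lower were Ffar2, a receptor for short-chain fatty acids (-2.08 ± 0.20), Pla2g7 (-1.76 ± 0.28), the phosphodiesterase gene Pde4d (-1.62 ± 0.22), and the RNA sensor gene Tlr3 (-1.52 ± 0.23). Terb1, Ackr2, Hs3st1 and Sema7a had differences between -1.36 and -1.31, and 1 of the other probe sets of Ackr2 gave -0.22. Cholesterol synthesis (0 of 14 called) and glycolysis genes (0 of 14) were called lower as lists, with adjusted p-values of 0.0017 and 0.0356, which became 0.177 and 0.418 with an estimated correlation. For the TNF receptor list (0 of 11) the adjusted p of 0.0413 became 0.243. In these 3 lists 0 members were called adjusted over the list alone; the largest differences were -0.59 for Idi1, -0.68 for Pkm and -0.37 for Tnfrsf1b.

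**Figure D1:**
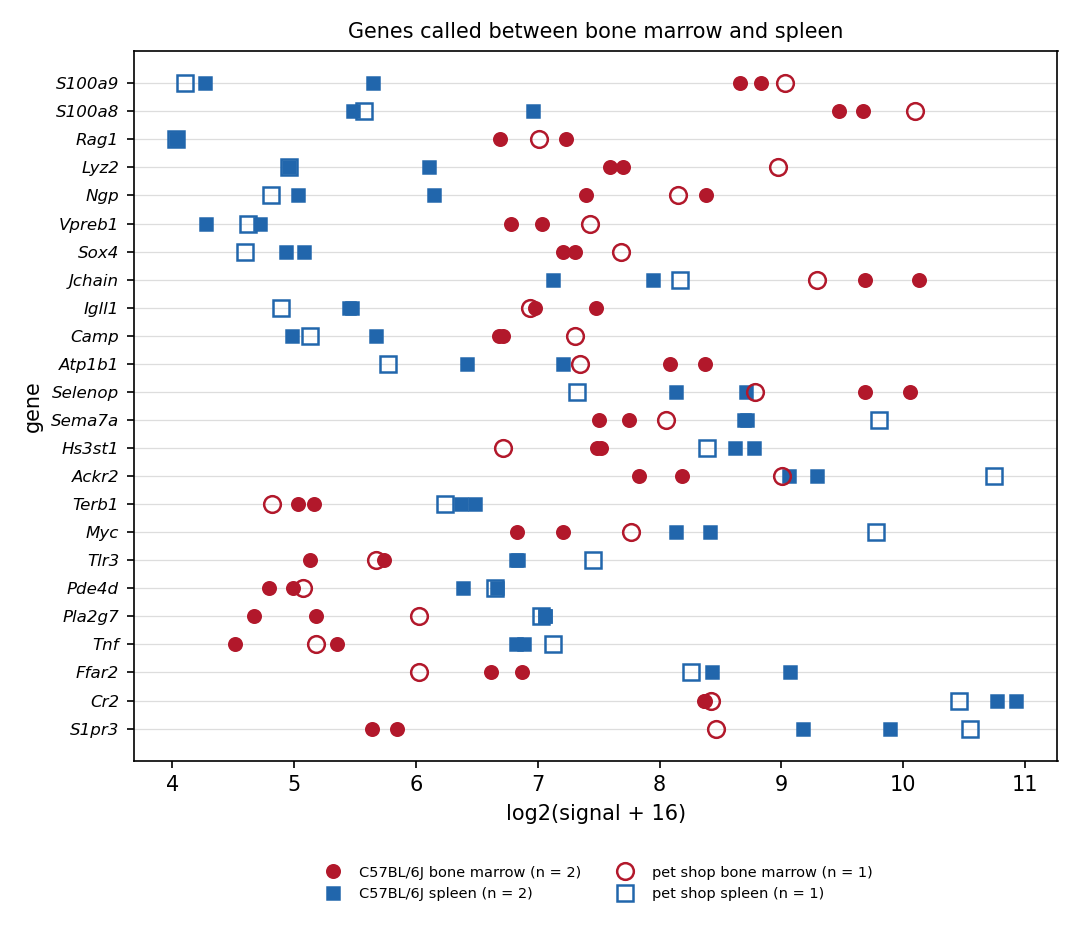
Each row is a named gene, the horizontal axis gives log2(signal + 16), and each symbol is 1 array: filled for C57BL/6J (n = 2 per tissue), open for pet shop (n = 1 per tissue), circles for bone marrow and squares for spleen. S100a9 lies at the top with a difference of 4.17 and S1pr3 at the bottom with -3.23.

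Genes of general B cell identity, by contrast, had a median difference of 0.00 (1 of 23 called, Cr2, and 1 adjusted over the list alone; adjusted p = 0.401). That median was -0.11 with quantile normalization and -0.01 with a common median. In all, camera called 13 of 28 lists, 6 higher and 7 lower in bone marrow, and the medians of these 13 kept their sign under both other scalings. With an estimated correlation it called 0, with 7 lists at an unadjusted p under 0.05, and fry called 9, of which 8 were among the 13 and the other was the immediate early list; it did not call the NF-kB, proliferation, monocyte, glycolysis and TNF receptor lists.

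The C57BL/6J arrays alone gave 34 calls, of which 30 had the same sign between the lone pet shop arrays, while across all genes the tissue differences of the origins correlated at r = 0.143. Of the 29 calls, leaving out C57BL/6J spleen 2 left 1, Cr2, and leaving out C57BL/6J bone marrow 1 left 11. Leaving out C57BL/6J bone marrow 2 gave 16 calls, of which 15 were among the 29. Without the 2 arrays with the highest Gapdh 3'/5' ratio the tissue estimate compares 1 C57BL/6J bone marrow array with 2 C57BL/6J spleen arrays. That fit has 1 residual degree of freedom, so its calls are no check on the effect of poor RNA. When either pet shop array is left out, the origin term fits the other exactly. Both omissions therefore take the tissue estimate from the 4 C57BL/6J arrays alone and are not separate checks. On these arrays the camera list calls of glycolysis (adjusted p = 0.776 without bone marrow, 0.773 without spleen), erythroid (0.0876 and 0.0844) and TNF receptor genes (0.123 and 0.123) ended. Without C57BL/6J bone marrow 1 the erythroid and TNF receptor lists gave 0.064 and 0.087. Without C57BL/6J spleen 2 TNF receptor genes gave 0.205.

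The second comparison sets pet shop against C57BL/6J arrays over both tissues. Xist, the noncoding RNA of the inactive X chromosome, was higher in pet shop arrays by 7.33 ± 0.20, and the Y-linked Eif2s3y, Kdm5d and Uty had differences of -5.65 ± 0.16, -3.71 ± 0.23 and -3.06 ± 0.22. Fos and Egr1, transcription factors induced within minutes of a stimulus, were higher by 3.37 ± 0.28 and 3.17 ± 0.21. limma called 566 of 9097 genes, 259 higher and 307 lower in pet shop arrays. With a common median for all arrays, which moved the median difference of all genes from 0.03 to 0.22, the same test gave 529 higher and 199 lower.

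The immediate early list had 10 members called higher and 1, Gadd45b, called lower among 25 (13 and 1 adjusted over the list alone); Gadd45b, at -1.03, was chosen after its value was seen. Jun (2.55 ± 0.34) and the phosphatase gene Dusp1 (2.93 ± 0.33) followed Fos and Egr1, whereas Cd69, at 0.10 ± 0.23, was not called. The list's adjusted p was 1.82e-06, and 0.275 with an estimated correlation. Its median of 0.71 became 0.71 with quantile normalization and 0.90 with a common median. The heat shock list, with 1 of 17 members called, Hsph1 at 0.87 (1 higher adjusted over the list alone), was not called (adjusted p = 0.0838).

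Antigen presentation genes held changes in both directions. H2-Ea, a class II chain that C57BL/6J mice are known not to transcribe, was higher by 6.66 ± 0.21, and the costimulatory gene Cd86 by 0.93 ± 0.16. H2-Eb1 and H2-DMb2 were lower, with differences of -2.29 ± 0.28 and -2.27 ± 0.20, and H2-Aa with -2.15 ± 0.41. Other probe sets gave -0.65 and -2.62 for H2-DMb2 and -0.89, -3.60 and 0.01 for H2-Aa, and under quantile normalization the difference of H2-Aa turned to 0.01 and was not called. Of 26 members 2 were called higher and 6 lower (3 and 8 adjusted over the list alone), with a list p of 0.0113 after adjustment, and 0.694 with an estimated correlation. B cell identity genes were called lower as a list (3 of 23 lower and 1 higher; 6 and 2 adjusted over the list alone), with Cd24a at -1.33 ± 0.24, Pax5 and Pou2f2 each at -0.83, and Syk at 0.87. Other probe sets had the opposite sign for Pax5 (0.46), for Pou2f2 (0.05) and for Syk (-1.78 and -1.31), while further ones of Pou2f2 and Syk had the same sign (-0.64 and 0.99). The adjusted p was 0.00615, and 0.575 with an estimated correlation. Cytosolic ribosomal protein genes had 24 of 25 negative differences with a median of -0.71, and 1 called member, Rps6 at -0.78 ± 0.15 (22 lower adjusted over the list alone). Their adjusted p was 6.39e-09, and 0.694 with an estimated correlation. Under quantile normalization the medians of the ribosomal, antigen presentation and B cell identity lists moved to 0.00, -0.06 and -0.18, and none of the 3 was called. With a common median they stood at -0.52, -0.20 and -0.22. Without pet shop spleen 1 the B cell identity list gave an adjusted p of 0.0572 and the antigen presentation list one of 0.0806. Neither was called with fry, with every probe set or without the 2 arrays with the highest Gapdh 3'/5' ratio, and the ribosomal list was not called with fry.

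Itgax, which encodes CD11c, was higher in pet shop arrays by 3.21 ± 0.43 although the sort had excluded CD11c-positive cells, with mean signals of 491 and 34.6. S1pr5, another sphingosine 1-phosphate receptor gene, was higher by 3.30 ± 0.41. In the memory B cell list Tbx21, encoding the transcription factor T-bet, was higher by 1.71 ± 0.28 and Cxcr3 by 0.82, while Ahr, the aryl hydrocarbon receptor, had a difference of -3.02 ± 0.18 and Pdcd1lg2 one of -0.87. With Cd86 the list had 3 called higher and 2 lower among 20 (5 and 2 adjusted over the list alone) and was not called (adjusted p = 0.221). In the monocyte, macrophage and dendritic cell list Itgax, Adgre1 (1.66) and Cd68 (0.99) were called higher and Hmox1 (-1.08) lower among 11 (3 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.319). Without pet shop bone marrow 1 the differences were 2.05 for Itgax, 0.97 for Tbx21, 0.56 for Adgre1 and -0.51 for Pdcd1lg2, and the last 2 were no longer called. Without pet shop spleen 1 the difference of Adgre1 was 2.76. The tissue difference of Itgax, Tbx21 and Adgre1 differed between origins, by 2.32 ± 0.46, 1.48 ± 0.31 and 2.19 ± 0.32. Interferon response genes were not called as a list either (adjusted p = 0.0612, and 0.694 with an estimated correlation). Usp18, Mx1 and Rsad2 were higher by 1.75, 1.46 and 1.07 and Ifi203 differed by -1.93 among its 24 members (6 higher and 2 lower adjusted over the list alone).

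Other genes with large differences were Pik3ap1 (3.34 ± 0.14), an adaptor of B cell receptor signalling, Ap1s3 (3.25 ± 0.24) and Fam234b (3.21 ± 0.28) among those higher. Lrwd1 (-3.70 ± 0.27), Trim34a (-3.62 ± 0.71), Vars (-3.30 ± 0.25), Ifi213 (-3.27 ± 0.22), Trim12a (-3.14 ± 0.58) and Zfp874a (-2.82 ± 0.22) were among those lower. A second probe set of Lrwd1 gave -0.15. Without pet shop spleen 1 the differences of Trim34a and Trim12a were -1.48 and -1.39, and without pet shop bone marrow 1 they were -5.75 and -4.88. Of 24 named origin genes with further probe sets of sufficient signal, 8 had at least 1 with the opposite sign or with under 33.3% of the size.

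**Figure D2:**
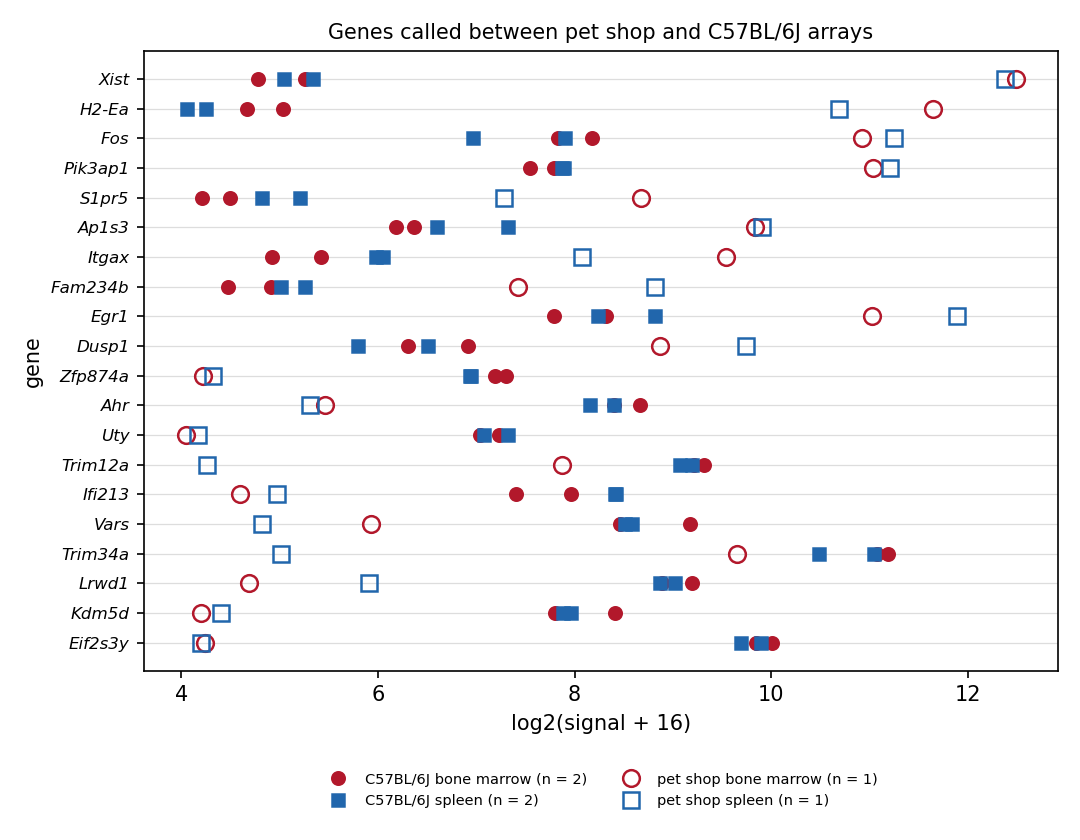
Each row is a gene named for the origin difference, the horizontal axis gives log2(signal + 16), and each symbol is 1 array: filled for C57BL/6J (n = 2 per tissue), open for pet shop (n = 1 per tissue), circles for bone marrow and squares for spleen. Xist and H2-Ea, with differences of 7.33 and 6.66, are at the top, and Eif2s3y, with -5.65, is at the bottom.

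The origin comparison rests on 2 pet shop arrays, and strain, Xist, the Y-linked genes, the 18S control signal and the wording of the sort in the titles all followed origin. Without C57BL/6J spleen 2 there were 180 calls and 33 of 64 named genes lost theirs. Leaving out either pet shop array leaves 1 of them to stand for the origin. Without the 2 arrays with the highest Gapdh 3'/5' ratio the origin estimate compares 1 pet shop with 1 C57BL/6J bone marrow array. That fit has 1 residual degree of freedom, so its calls are no check on the effect of poor RNA here either.

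The third comparison asks whether the tissue difference itself differed between origins. Pet shop spleen 1 stood apart from the other 5 arrays for all 6 genes named here. Trim34a, Trim30d and Trim5, members of the tripartite motif family, had little tissue difference in C57BL/6J arrays (0.37, -0.06 and 0.27), while pet shop bone marrow exceeded pet shop spleen by 4.64, 4.03 and 4.62. The differences of these differences were 4.27 ± 0.35, 4.09 ± 0.35 and 4.35 ± 0.40 (SE). In the opposite direction Gdpd3 differed by -5.82 ± 0.63, Mid1 by -4.23 ± 0.51 and the peptide transporter gene Slc15a2 by -3.86 ± 0.58. limma called 69 genes, 52 with a more positive and 17 with a more negative tissue difference in pet shop arrays.

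**Figure D3:**
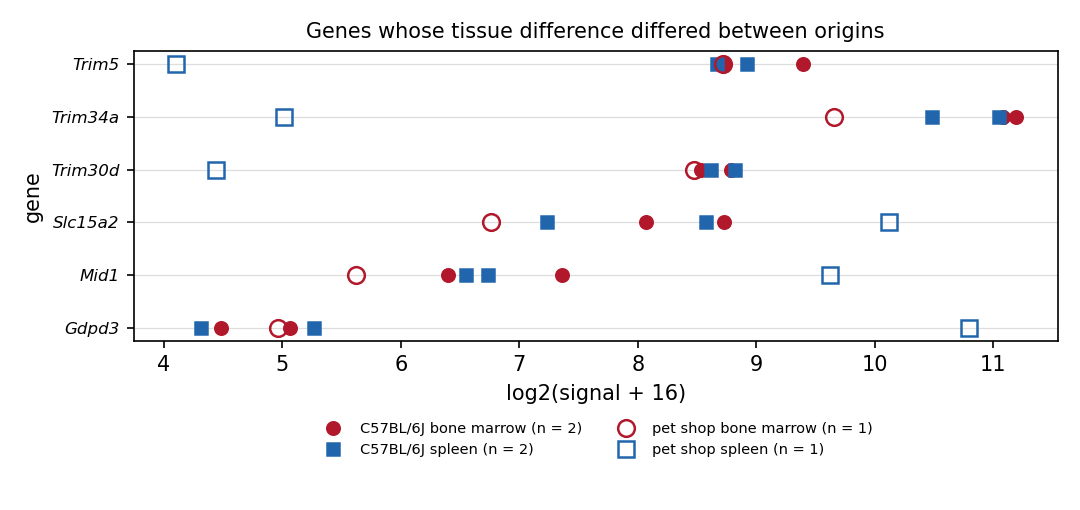
Each row is a gene named for a tissue difference that differed between origins, the horizontal axis gives log2(signal + 16), and each symbol is 1 array: filled for C57BL/6J (n = 2 per tissue), open for pet shop (n = 1 per tissue), circles for bone marrow and squares for spleen. The open square of pet shop spleen 1 lies outside the other 5 arrays in every row.

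Each pet shop tissue is a single array, so these values hold for 2 arrays and not for pet shop mice in general, and pet shop spleen 1 was also the array with the Gapdh 3'/5' ratio of 68.8. The count was 28 without C57BL/6J spleen 1, 140 without C57BL/6J bone marrow 1 and 310 without C57BL/6J bone marrow 2.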

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

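In the results below the tissue difference of a gene differed between pet shop and C57BL/6J arrays in a test of that difference itself, over all genes that the naming rule took for any comparison. None of these tests was chosen after the result was seen. However, the naming rule took Trim34a, Trim30d, Trim5, Gdpd3, Mid1 and Slc15a2 by the smallest p of this same test. Their passing it is therefore no separate evidence. Each value compares 1 pet shop pair with 2 arrays per tissue of C57BL/6J. Trim34a (4.27), Trim30d (4.09), Trim5 (4.35) and Trim12a (3.48) had a more positive tissue difference in pet shop arrays, and Gdpd3 (-5.82), Mid1 (-4.23) and Slc15a2 (-3.86) a more negative one. With no filter on low values 6 genes were called, all with a more positive tissue difference in pet shop arrays. Gdpd3, Mid1 and Slc15a2, and Nid1 and Bid described below, were thus no longer called. Slc15a2 was also not called without a trend in eBayes, with robust estimation or with every probe set. Trim34a, Trim30d and Trim5 were called in all 13 alternatives run for them. Among genes of the lists, Adgre1 and Itgax of the monocyte, macrophage and dendritic cell list differed by 2.19 ± 0.32 (SE, adjusted p = 0.00837) and 2.32 ± 0.46 (adjusted p = 0.0321), and Tbx21 of the memory B cell list by 1.48 ± 0.31 (adjusted p = 0.0448). Slfn2 of the quiescence list differed by 2.14 ± 0.32 (adjusted p = 0.00876): it stood at 0.06 between C57BL/6J tissues and 2.20 between pet shop tissues. Nid1, of the B-1 cell list, differed by -1.82 ± 0.30 (adjusted p = 0.0152), with 0.99 in C57BL/6J and -0.83 in pet shop arrays. Bid, a death-promoting member of the BCL2 family, differed by -1.48 ± 0.31 (adjusted p = 0.0431), with -0.20 and -1.68. No group held enough arrays to test single arrays as outliers.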

How the results depend on the processing

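The actin covariate, the crossed replicate block and the omission of 2 arrays were chosen after seeing the data. Signal over background could not be judged, since no detection calls were used here. Over all alternatives, 174 named gene results stayed on their side of the threshold in 2837 cases. They lost a call in 424, gained one in 13 and reversed in 1. For 56 list results these counts were 1081, 59, 51 and 1. The 2837 and the 1081 include results that were not called and stayed so, and thus overstate how often a call was kept. The reversals were H2-Aa by origin under quantile normalization, at 0.00734, and the granulocyte list by origin without the 2 arrays with the highest Gapdh 3'/5' ratio, at an adjusted p of 0.0294 (0.0294 to 0.996 over its alternatives). Against 29 tissue calls there were 9 with no filter on low values, 14 in the upper 30%, 15 without a trend in eBayes, 13 with every probe set, 6 with no origin term, 11 with an actin 3'/5' covariate and 56 without the 2 arrays with the highest Gapdh 3'/5' ratio, and 1 to 37 with single arrays left out. Replicate numbers pair nothing by the labels. The C57BL/6J difference between replicates 1 and 2 in bone marrow and that in spleen correlated at r = -0.238 across genes; with the pet shop pair as 1 block, whose titles bear different numbers, a replicate block gave 13 calls and a crossed replicate block 19. With these blocks 13 and 14 tissue lists were called. Against 566 origin calls there were 238 with no filter, 343 in the upper 30%, 979 with every probe set (347 with a probe set higher and 654 with one lower) and 214 with the actin covariate, and 180 to 499 with single arrays left out. Against 69 calls for the difference of tissue differences there were 41 with quantile normalization, 39 with a common median, 6 with no filter, 13 without a trend and 15 with every probe set, and 28 to 310 with single C57BL/6J arrays left out; it could not be fitted without either pet shop array. Against 13 tissue lists, 0 were called with an estimated correlation and 3 in the upper 30%. Against 4 origin lists, 0 were called with an estimated correlation, 1 with fry, 7 with no filter and 8 without the 2 arrays; quantile normalization called 3, sharing 1. The upper 30% holds fewer genes and each omission fewer arrays. Without the 2 arrays with the highest Gapdh 3'/5' ratio, 1 pet shop array and 1 C57BL/6J bone marrow array are left. Calls of that fit are therefore no check on either comparison. Otherwise the cause was not tested.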

Other observations

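Of the tests below, those of RNA imbalance, of other cell types in either sort, of dilution, of genes called by a further probe set alone, of the 18S signal and of neighbouring genes were chosen after the result was seen.

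Several list genes not yet described differed by origin. None of the lists in this paragraph was called. In the marginal zone list Cd9 (-2.49 ± 0.20) and S1pr1 (-1.15 ± 0.25) were lower and S1pr3 (1.87 ± 0.35) and Tm6sf1 (1.12 ± 0.22) higher in pet shop arrays (list adjusted p 0.544; the values in brackets after later lists are the same measure). Homing receptor genes went both ways: Ccr9, a receptor for gut homing, had -1.64 ± 0.23, and the cannabinoid receptor gene Cnr2 had 1.12 ± 0.22 (0.909). Among adhesion genes (0.721) Cadm1 (-1.18), Alcam (-0.87) and Itgb2 (0.94) were called, although another probe set of Alcam gave 0.28. Among glycolysis genes (0.85) Pdk1 (-1.17) and the glucose transporter gene Slc2a3 (0.96) were called, and among B cell receptor signalling genes (0.15) Malt1 (0.86) beside Pik3ap1 and Syk. The stem cell factor receptor gene Kit had -1.74 and Hmgb2 -0.92, in the pro-B and pre-B list (0.0612), although another probe set of Hmgb2 gave 0.00. The quiescence genes Slfn2 (-2.26), Txnip (-0.87) and Ccng2 (-0.62) were lower (0.0859), and the clock genes Bhlhe40 and Nr1d2 stood at 0.91 and -0.64 (0.544). Single calls were Mzb1 (-0.72) of the plasma cell list (0.221), Neil1 (0.85) of the germinal centre list (0.85), Icam1 (0.57) of the NF-kB list (0.544), Nusap1 (-0.97) of the proliferation list (0.85) and Uqcrq (0.76) of oxidative phosphorylation (0.583). The B-1 cell, granulocyte, erythroid, TNF receptor, BCL2 family, Notch and cholesterol lists held no called gene, and their adjusted p-values were 0.909, 0.822, 0.85, 0.909, 0.544, 0.319 and 0.544. Without pet shop bone marrow 1 the differences of S1pr3 (1.01), Tm6sf1 (0.59), S1pr1 (-0.74), Cnr2 (0.71), Itgb2 (0.60), Pdk1 (-0.62) and Bhlhe40 (0.54) were no longer called, and without pet shop spleen 1 that of Slfn2 was -1.19.

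Ighm, the IgM constant region gene, was higher in pet shop arrays by 1.47 ± 0.23 (adjusted p = 0.00759) although the sort had excluded IgM-positive cells; it was chosen after its value was seen.

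Between tissues, lists without a call included germinal centre genes (adjusted p = 0.065), ribosomal genes (0.0509, median 0.11, which turned to -0.04 with quantile normalization), interferon response (0.17), oxidative phosphorylation (0.152), adhesion (0.911), the BCL2 family (0.507), B cell receptor signalling (0.435), memory B cells (0.328), B-1 cells (0.158), heat shock (0.152), antigen presentation (0.594) and the circadian clock (0.226). With an estimated correlation the smallest was 0.265. Lists for T cells, natural killer cells, megakaryocytes, stromal cells, immunoglobulin constant regions and sex-linked genes had fewer than 5 tested members and were not tested as lists.

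The 12 genes higher in bone marrow held 8 from the granulocyte and B cell precursor lists. Without C57BL/6J bone marrow 1 the median difference of the 12 was 2.48 (1.35 to 4.22), so their differences did not come from that array alone. However, the 12 were called over the same arrays, which favours genes high on all 3 bone marrow arrays. This test could therefore hardly have failed and does not decide on RNA imbalance. The fit also still held pet shop spleen 1, with its Gapdh 3'/5' ratio of 68.8. Whether cells of other types entered the bone marrow sort stays open. Beside the 8 called members that prompted the question, 6 of 9 (66.7%) were higher in both origins, where chance gives 25%. With estimated correlations of up to 0.874 the 95% interval of this share, 0.519% to 100%, was too wide to decide. No other count of so few genes could have decided either, so the share speaks neither for nor against such cells. The gate on CD19 and IgG2b would remove such cells, and at mean signals of 857 for S100a8 and 111 for Rag1 their share cannot be derived from the arrays. Expression of these genes in memory B cells of the bone marrow was not tested and stays open.

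For the genes lower in bone marrow, dilution by cells that lack B cell and antigen presentation genes would lower most of those genes alike. The 46 B cell identity and antigen presentation genes other than Cr2 and Cd83 had a median of 0.00626 (quartiles -0.181 and 0.137). The called genes had one of -1.36, which argues against dilution by such cells. Precursor B cells and monocytes could carry some of the 46 genes, so for dilution by them the test cannot decide. Marginal zone type cells in the spleen sort stay open: 53.8% of 13 list members were lower in both origins (95% interval 25.1% to 80.8%), and 4 of the 10 not called themselves (40.0%). The gate against IgM and IgD would not remove such cells once they had switched to IgG2b. IgM-positive cells in the spleen sort stay open too, although that gate would remove them. The difference of Ighm was 0.709 ± 0.221 and not called, but precursor cells in bone marrow could carry Ighm of their own. A true difference of memory B cells between tissues was not separated from these.

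For the genes that differed by origin, sequence variants under single probe sets would make genes lower in pet shop arrays less reproducible between probe sets than genes higher in them. Other probe sets had the same sign and at least 33.3% of the size in 58.4% of 238 cases for lower genes and 53.5% of 187 for higher genes, a ratio of 1.09. With the authors' scaling this prediction was not met. The test covers the 139 of 307 lower genes with another probe set and cannot see variants that lower several probe sets of a gene. It therefore does not exclude variants as a source of the lower calls of representing probe sets. A common median changed the balance of higher and lower calls, and the ratio was not computed under other scalings. Among genes called by a further probe set alone, 73.7% were lower in pet shop arrays (368 against 131), 73.3% with quantile normalization and 57.3% with a common median, so for these calls variants stay open. A labelling or hybridisation batch that follows origin cannot be told apart from origin: the lowest C57BL/6J 18S signal was 6.73 times the highest pet shop one, and no batch is known that holds both. Strain, sex, living conditions and a sort that differed between origins are untested, cannot be told apart from origin here and stay open as well. For sex, Xist was higher and 3 Y-linked genes were lower in pet shop arrays. Of the 566 origin calls, 546 lay on autosomes, 14 on X and 3 on Y.

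A hypothesis for the genes whose tissue difference differed between origins is that the mice behind the 2 pet shop arrays carried different germline alleles. Calls would then bunch along chromosomes, and 19 of 69 called genes had another called gene among the 5 next tested genes on either side, against a median of 4 and at most 18 in 10000 random draws. In the same test 298 of 563 genes called by origin had such a neighbour (median of the draws 265, 95th percentile 287), and 4 of 29 called by tissue (median 0, 95th percentile 4). Trim34a, Trim5, Trim12a and Trim30d were among the 19, and so were the immunoglobulin genes Igha and Ighg3. Neighbouring genes that are regulated together, or related genes that share probes, may bunch in the same way and were not tested. A different mix of cells in the 2 sorts and the RNA imbalance of pet shop spleen 1 (Gapdh 3'/5' ratio 68.8) were not separated from the hypothesis either.

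Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split called 29 genes and the other splits at most 0, so 1 of 10 reached the real count. For lists, 2 of the 10 splits reached the 13 of the real one, and the highest other called 14, that of both C57BL/6J bone marrow arrays with C57BL/6J spleen 1 against the rest.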
